A study of Drosophila melanogaster with 36 samples.

How the data were processed

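Gut RNA was sequenced from 36 pools of w1118 fruit flies, in 12 groups of 3 libraries that cross sex with 6 conditions. Per the labels' protocols, each library came from 20 pooled guts, dissected with foregut, midgut, hindgut and Malpighian tubules. Founders were mated flies taken at 2 days of age, and the other groups ate a control diet or a diet with 1 phytochemical for 10 days at 25 °C. The diets held capsaicin at 2 mM, curcumin at 200 µM, resveratrol at 10 µM or thymoquinone at 100 µM, and the control diet held the same share of the ethanol vehicle. The libraries were poly(A)-selected and kept strand information through dUTP, per the labels' protocols, and were read on a NovaSeq X Plus.

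The deposited table holds whole-number counts of reads per gene, which the authors made with HISAT2 2.2.1 and featureCounts 2.0.6 on the BDGP6 genome, per the submitters' processing notes. These notes also name DESeq2 1.50.2. The annotation release, the strand setting of the counting and the treatment of reads with several positions are not given in the sources used here. Antisense genes and genes that overlap others are therefore uncertain. The same holds for families with near-identical copies, such as lysozymes, Jonah proteases, trypsins, amylases, accessory gland peptides and actins.

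The table lists 23932 features, of which 5578 are transposable elements and 6469 had no count in any library. Gene names were taken from the table, and 5 symbols that a spreadsheet had turned into dates were restored through the gene identifier. A spreadsheet had also turned 18 chromosome cells into numbers. Of the 23851 identifiers shared with the reference annotation, 23812 had the same chromosome, start and end, and positions are given as in the table. The total per library ran from 11.7 to 30.2 M counts (M, mega), with a median of 19.2 M. The closest pair of replicates differed by 44.7 in chi-square per degree of freedom over genes, far beyond sampling noise, so that no library was counted as a copy of another.

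Genes were kept by edgeR's filterByExpr with the 12 groups, which left 12855 features, 11694 of them protein coding. Counts were scaled by the trimmed mean of M values (TMM) and tested with edgeR 4.0.16 (robust quasi-likelihood fit and test, R 4.3.3) in 1 fit of all 36 libraries with 24 residual degrees of freedom. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within its comparison. Levels are CPM on TMM-scaled library sizes, as mean ± SD of 3 libraries. Sums of organ lists and the levels given beside them in the paragraph on reproductive organs are CPM of total counts instead, and each pair of group sums compared in the text had the same order with TMM scaling. Errors of log2 fold changes are standard errors from the test. A fold against a group with 0 counts in all libraries is given as a lower bound, with the empty group set at 3 counts over its 3 libraries. Such bounds cover counting error only. P-values measure the spread between pools of guts. The labels call the pools biological replicates and do not say whether they came from separate cultures.

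The 17 comparisons were each diet against control within a sex, control against founder within a sex, female against male in founders and in controls, and the differences between the sexes in the diet and age effects. The genes called in at least 2 diets and the covariance of fold changes between the sexes were added to these. In total 46 gene lists, fixed before the data were examined, were tested with limma's camera (limma 3.58.1) on log2 CPM with a prior count of 2, at a preset correlation of 0.01 and again with an estimated correlation. Adjusted p-values of lists are over all lists of a comparison. For members of a list, p-values were also adjusted over the list alone.

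Genes to be named were fixed by a rule before the data were examined. The rule takes called genes with at least 5 CPM in the higher group and non-overlapping libraries, up to 10 per direction for diets and age and up to 5 for sex and interactions. Interactions need no separation of libraries. Where fewer than 3 genes passed, it takes the 3 with the smallest p, and it adds the 4 members of each list with the smallest p. The genes and lists named in the text were picked from these sets after their values were seen, and counts over all lists are given beside them.

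The labels give each library a batch value equal to its replicate number, so the numbers were taken to pair libraries across groups. Deviations of libraries from their group means did not follow this pairing. Their correlation between libraries with the same number had a median of −0.00835 (range −0.726 to 0.652), with 46 of 198 pairs over 0.1, against a median of 0.00188 for libraries with other numbers. Of 36 libraries, 7 correlated best with a library of their own number. A fit with the replicate block was an alternative set in advance.

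Other alternatives set in advance were DESeq2 1.42.0, median-of-ratios size factors, no filter, a filter at 5 CPM in 3 libraries, a fit of only the groups compared, a log2 fold change of at least 1, and leaving out each library in turn. Alternatives chosen after the data were seen were limma on log2 CPM, limma voom with sample quality weights under both filters, and the mitochondrial share of counts as a covariate under both filters. Further ones were genes with at least 20 CPM in 30 libraries, DESeq2 with its filtering tuned at 0.1, and a fit without the 3 libraries that had over 500 unseen genes. An unseen gene had 0 counts in a library and at least 50 in both other libraries of its group.

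The steps were tested on simulated libraries with the measured means, depths and spread, in which 200 genes per diet comparison were changed. Over 10 simulations of all 8 diet comparisons with 12290 genes tested, edgeR recovered 2.44% of the genes changed 2-fold, 34.8% of those changed 4-fold and 69.1% of those changed 8-fold, and 3.14% of its calls were false. DESeq2, run on 2 simulations with 12855 genes, recovered 11.4%, 57.1% and 82.4%, and 23.7% of its calls were false. Limma voom with quality weights recovered 3.17%, 34.8% and 64.1%, and 20.8% of its calls were false.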

Results

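The data are counts of reads per gene in the guts of female and male flies that were taken as 2-day-old founders or after 10 days on a control diet or on a diet with capsaicin, curcumin, resveratrol or thymoquinone. Each of the 12 groups held 3 libraries, and the total per library lay between 11.7 and 30.2 M counts. Replicates differed widely. The biological coefficient of variation over all genes was 74.7%, and the share of counts from mitochondrial genes ran from 6.23% in a female library on capsaicin to 60.6% in female curcumin 2. That library had 0 counts for 911 genes with at least 50 counts in both of its replicates, while male thymoquinone 2 and male founder 3 had 588 and 519 such genes. The median over all libraries was 2.5.

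**Figure D1:**
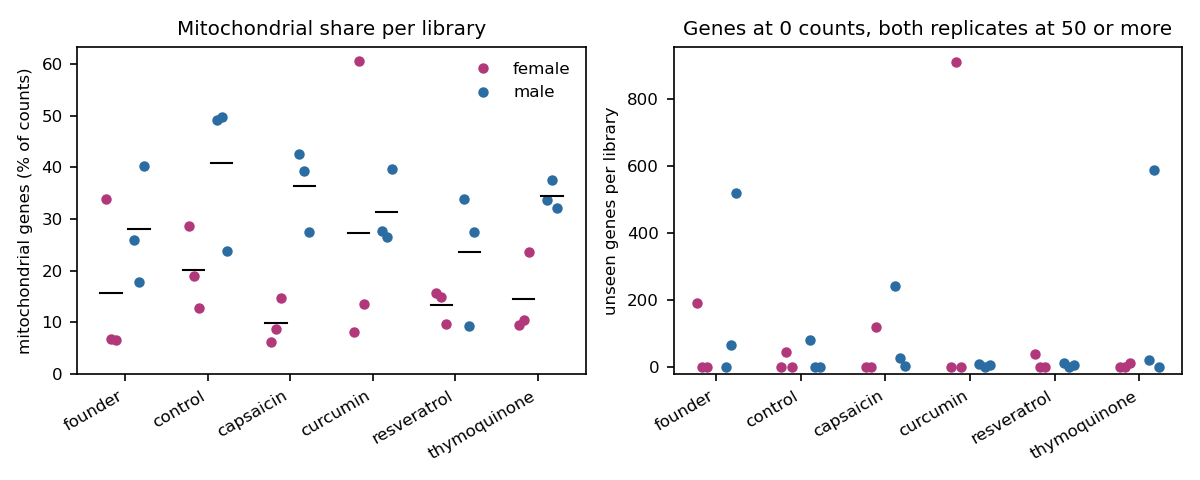
Left, mitochondrial genes as a percent of all counts. Right, the number of genes with 0 counts in a library and at least 50 in both other libraries of its group. Points are libraries and lines (left panel) are means of 3 libraries. The share reached 60.6%, and 3 libraries had over 500 unseen genes.

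Transcripts of reproductive organs were present in many gut libraries and differed between replicates of 1 group by orders of magnitude. Levels here and all sums of organ lists are CPM of total counts, without TMM scaling. The 29 genes of the ovary and egg list, such as those of the eggshell, summed to between 11.9 CPM in female control 2 and 15191 CPM in female founder 3. In female controls the sum was 1273 ± 1514 CPM (SD, n = 3), and on resveratrol it was 181 ± 184 CPM. The testis list summed to 2.99 to 1572 CPM in males. The accessory gland list summed to 1899 to 32318 CPM in males and 227 to 736 CPM in females. In females 2 of its 31 genes reached a median of 1 CPM. In male resveratrol 2 the ovary list reached 205 CPM, the highest of the male libraries, beside 59.0 CPM of the sex determination gene Sxl, which had a median of 1.50 CPM in males and 88.6 CPM in females. The male dosage compensation RNA lncRNA:roX1 was also highest in this library, at 236 CPM. The yolk protein gene Yp1 lay at 771 CPM or more in all female libraries and at 3.71 CPM or less in all male libraries, male resveratrol 2 included.

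**Figure D2:**
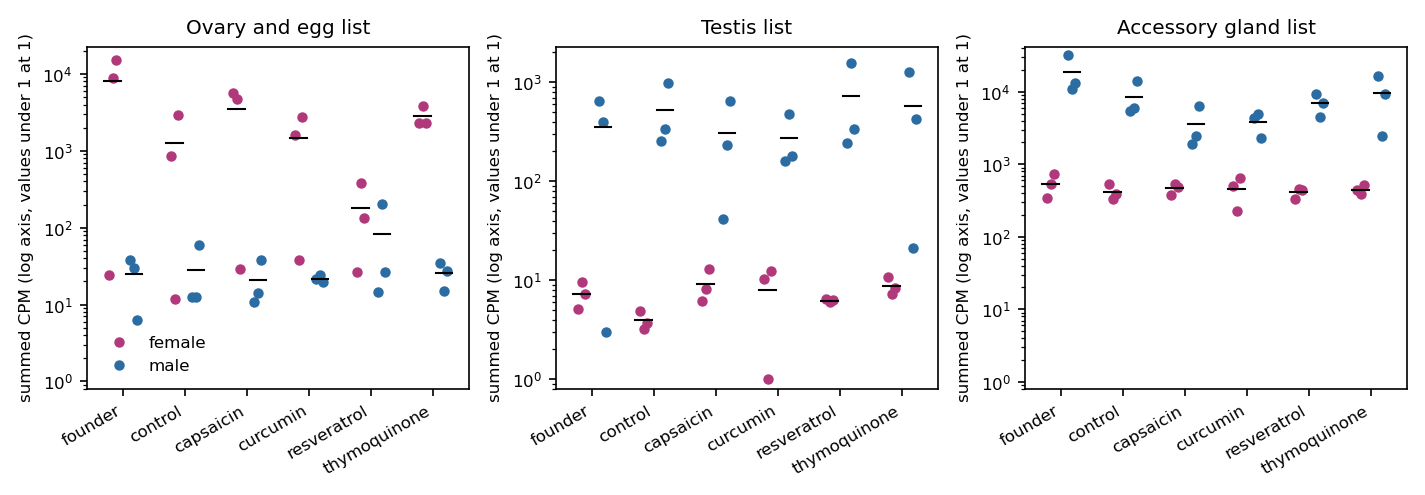
Summed CPM of the ovary and egg, testis and accessory gland lists in each library, without TMM scaling, on log axes, with values under 1 drawn at 1. Points are libraries and lines are means of 3. Female libraries of the same group differed in the ovary list from 11.9 CPM to 2953 CPM in controls and from 24.0 CPM to 15191 CPM in founders.

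Female and male founders were compared to check the labels and to describe how the gut differed between the sexes before the diets. Yolk protein genes were higher in females. Yp1 lay at 1843 ± 724 CPM in females and 0.336 ± 0.582 CPM in males, Yp3 was 8.05 ± 0.78 higher on the log2 scale, and Yp2 was at least 27012-fold higher. Sxl, the switch gene of female development, was 4.57 ± 0.82 higher in females on the log2 scale (adjusted p = 0.00314). The dosage compensation RNAs lncRNA:roX1 and lncRNA:roX2 were lower in females by log2 fold changes of −5.37 ± 1.13 and −7.90 ± 1.43. The antisense gene asRNA:CR45601 was at least 2968-fold higher in females, but it lies within the span of Yp1 on chromosome X and cannot be told from it without the strand setting.

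All 31 members of the accessory gland list had lower estimates in female founders, with a median log2 difference of −7.56 (−8.94 with the 15 members that had an empty group at their bound). This list and the 4 others of this paragraph passed with the preset correlation, and each had adjusted p = 0.571 with an estimated correlation. Seminal fluid genes such as Obp56g and Acp24A4 were at least 82346-fold and 29092-fold lower. Of 31 testis genes, 23 were called lower in females, with a median of −4.47 (−5.75 at bounds), and betaTub85D, the testis tubulin, lay at 0.0251 ± 0.0435 CPM in females and 67.9 ± 69.9 CPM in males. Of 29 ovary genes, 11 were called higher in females and 27 when adjusted over the list alone. The median was 6.15 (7.67 at bounds), and the eggshell genes Vm26Ab, Cp16 and Cp18 were at least 5200-fold, 2064-fold and 1705-fold higher. Of 90 genes of the nuclear respiratory chain list, 18 were called lower in females. The 4 with the smallest p were ND-B14.5AL, ATPsynGL, COX5BL and COX7AL, which are named as paralogs of respiratory chain subunits, and ATPsynGL was at least 241-fold lower, with libraries of both sexes at or near 0. Male founder libraries held testis transcripts (list sum 349 ± 325 CPM), and whether the 18 calls follow them was not tested. Among 35 glutathione S-transferases, which conjugate toxic compounds, 6 were lower in females and 11 over the list alone. GstD2 lay at 21.8 ± 9.57 CPM in females and 161 ± 102 CPM in males. The cytochrome P450 gene Cyp312a1 and the sterol-binding gene Npc2b were also lower, by −6.10 ± 1.01 and −2.08 ± 0.34.

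In all, edgeR called 1163 of 12855 genes between founder females and males, 90 higher and 1073 lower in females, relative to a median log2 shift of −0.15. With median-of-ratios size factors this shift was −0.06. How many of the genes called between the sexes, here and in controls, follow transcripts of reproductive organs was not tested. Of 46 lists 16 passed camera with the preset correlation and 0 with an estimated one. In the comparison founder female vs male, the count fell to 32 without female founder 2, 33 without female founder 3, 275 without male founder 1, 521 with the replicate block and 61 in a fit of the founders alone. The share higher in females was 7.74% in the fit of all groups, 37.7% in the fit of the founders alone and 21.3% by DESeq2, which called 1985. Yp1, Yp2, Yp3, Sxl, Obp56g, Cyp312a1 and Npc2b kept their calls without any 1 library. Vm26Ab, Cp16 and Cp18 lost theirs without any library but female founder 1 (adjusted p up to 0.144), with the block (0.0631, 0.0631 and 0.0804), with no filter and with the mitochondrial share as a covariate. lncRNA:roX1, Acp24A4, betaTub85D, GstD2 and the 4 respiratory chain paralogs lost theirs without female founder 2 or 3 (up to 0.108), lncRNA:roX2 without female founder 2 (0.0754) and COX5BL also without male founder 1 (0.0511 for COX5BL, founder female vs male). Limma on log2 CPM did not call COX5BL and COX7AL. With the founders alone, Npc2b had 0.062 and GstD2 0.114. Single libraries moved Sxl (3.93 without female founder 2), lncRNA:roX2 (−9.38 without female founder 3), GstD2 (−2.89, −2.25 without male founder 3), COX5BL (−7.68, −9.85 without female founder 2 and −6.53 without male founder 1) and, at few counts in the lower group, Yp1 (12.73, 18.32 without male founder 3) and betaTub85D (−10.82, −13.50 without female founder 2). Without male founder 1, 2 or 3 the medians were −5.18, −10.54 and −6.35 for accessory gland and −2.97, −3.32 and −6.77 for testis, and without female founder 1, 2 or 3 that of ovary was 8.29, 5.0 and 4.54. Without female founder 2 the glutathione S-transferase median of −1.65 was −1.01 and the respiratory chain median of −1.30 was −0.76, and the latter was −1.90 without female founder 1.

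After 10 days on the control diet the sexes differed in the same marker genes. Yp1 lay at 1217 ± 301 CPM in females and 0.138 ± 0.238 CPM in males, and lncRNA:roX1 at 0.0299 ± 0.0519 and 60.4 ± 13.6 CPM. Sxl was 3.2 ± 0.76 higher in females. Send1, a serine protease gene of the spermatheca, and the serine protease gene Ser12 were at least 1071-fold and 1101-fold higher in females. Seminal fluid genes were lower in females, with Sfp87B and Sfp60F at least 98155-fold and 66420-fold lower, and the ejaculatory bulb gene Ebp lay at 0.00998 ± 0.0173 CPM in females and 2470 ± 903 CPM in males. All 31 accessory gland genes (median −9.58, −10.80 at bounds) and 25 of 31 testis genes (median −7.14, −8.25 at bounds) were called lower, and both lists had adjusted p = 0.855 with an estimated correlation.

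Digestive and immune genes also differed between control females and males. Of 16 Jonah proteases, digestive enzymes of enterocytes, 4 were higher in females and 9 over the list alone, with a median of 2.34. The Jonah, DNA replication and ovary lists had adjusted p = 0.866 with an estimated correlation. Jon99Fi was 4.92 ± 1.27 higher on the log2 scale and Jon66Cii 4.24 ± 1.06 higher. Of the 27 genes for DNA replication and mitosis, 4 were higher in females and 12 over the list alone (median 2.05), with CycA, a mitotic cyclin, at 43.2 ± 60.8 CPM in females and 2.71 ± 1.74 CPM in males and RnrL, a subunit of ribonucleotide reductase, at 41.8 ± 43.8 and 5.65 ± 4.47 CPM. Of 29 ovary genes, 6 were higher and 14 over the list alone (median 3.39, 4.82 at bounds). The antifungal peptide gene Drs was higher in females, at 711 ± 301 against 37.7 ± 32.3 CPM, and the cecropin gene CecA1 was lower, at 0.220 ± 0.203 against 20.8 ± 8.48 CPM. The detoxification genes Cyp6w1 and GstS1 were lower in females by −2.57 ± 0.45 and −2.76 ± 0.63, and LysB was higher by 4.22 ± 1.11.

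For control female vs male, edgeR called 1723 genes, 112 higher and 1611 lower in females, against a median log2 shift of −0.13 (−0.17 with median-of-ratios size factors). DESeq2 called 2371 and limma on log2 CPM 2106. Of 46 lists, 13 passed with the preset correlation and 0 with an estimated one. Without female control 1, 2 or 3 the count was 268, 620 and 101. Sfp87B (adjusted p = 0.0549), Ebp (0.0555), Sxl (0.0761), GstS1 (0.0608), CecA1 (0.0701) and Drs (0.0585) lost their calls without female control 3. Jon66Cii (0.0645) lost its call without female control 2, and Jon99Fi (0.0537), LysB (0.0603), CecA1 (0.0603) and Drs (0.0624) without female control 1. CycA lost its call without any library but female control 2 (up to 0.554), and RnrL without female control 1 or 3 or male control 1 (up to 0.306); neither was called with the mitochondrial share as a covariate or in a fit of the controls alone, nor CycA with the block, with no filter or by limma on log2 CPM. Drs also lost it without male control 2 (0.058) or 3 (0.0507), and LysB in a fit of the controls alone (0.0537). Without female control 3 the medians were 0.32 for ovary and 0.78 for DNA replication, with Sxl at 2.47, CycA at 1.57 (3.96 with all libraries) and RnrL at 1.54 (2.88), and the Jonah median was 3.26. Without female control 2 the medians were 1.55 for Jonah, 4.53 for ovary and 2.95 for DNA replication (1.44 without male control 1), and Jon66Cii had 3.14. Without single male controls Jon99Fi had 5.58 (male control 1), Drs 5.19 against 4.24 (male control 1), Jon66Cii 4.88 and LysB 5.15 (male control 2). CecA1, −6.62 with all libraries, had −7.40 without female control 2 and −5.96 without female control 3, and at few counts in the lower group Yp1 had 17.70 (12.60) without male control 3 and lncRNA:roX1 −13.34 (−10.34) and Ebp −18.69 (−16.91) without female control 3.

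In males, 3 genes fell between the 2-day-old founders and flies that had spent 10 days on the control diet. Lsp1gamma (FBgn0002564, chromosome 3L, 66430 to 68995) encodes a larval serum protein, a storage protein of the larval fat body. It lay at 168 ± 125 CPM in founders and 0.214 ± 0.371 CPM in controls, a log2 fold change of −9.21 ± 1.40 (adjusted p = 0.00308). LysB (FBgn0004425, chromosome 3L, 1207371 to 1207981), a digestive lysozyme gene with close copies, fell from 239 ± 89.7 to 0.548 ± 0.597 CPM, by −8.75 ± 1.31 (0.00308). CG4835 (FBgn0035607, chromosome 3L, 5479790 to 5483663) fell from 98.7 ± 43.5 to 1.85 ± 1.34 CPM, by −5.69 ± 1.0 (0.0164). For each gene all 3 founder libraries lay above all 3 control libraries.

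Several groups of genes moved with these in males. All 6 lysozymes had lower estimates, 4 of them passing when adjusted over the list alone and 1 over all genes, with a median of −2.70 (−2.75 at bounds). LysE lay at 328 ± 138 CPM in founders and 53.0 ± 14.1 CPM in controls. The 5 flight muscle genes also had negative estimates, with a median of −1.18. Act88F, the flight muscle actin, lay at 12.7 ± 3.35 CPM in founders and 0.118 ± 0.109 CPM in controls, and Mlp84B had −1.06 ± 0.31. Both lists passed with the preset and with an estimated correlation (adjusted p = 0.000794 for each with an estimated correlation). Visceral muscle genes (median −0.96) and regulators of the Imd immune pathway (median −0.58) passed with the preset correlation and had adjusted p = 0.0788 and 0.0716 with an estimated correlation. Of 19 Imd genes 3 passed over the list alone, among them PGRP-SC1a (537 ± 236 to 33.7 ± 13.4 CPM), an amidase that degrades peptidoglycan, and pirk (71.6 ± 21.6 to 28.9 ± 13.6 CPM), an inhibitor of the pathway.

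Iron and stress genes in males passed only when adjusted over their own lists. The ferritin genes Fer1HCH and Fer2LCH had log2 fold changes of −1.72 ± 0.38 and −2.12 ± 0.47, and the iron carrier gene Tsf1 had 2.01 ± 0.56. Fer1HCH lay at 2714 ± 508 CPM in founders and 821 ± 35.1 CPM in controls. The small heat shock gene Hsp23 had −2.41 ± 0.54, the antibacterial peptide gene AttD −4.21 ± 1.07 and the glutathione S-transferase GstD2 −2.65 ± 0.60. Jonah proteases had a median of −1.82 and the testis list a median of 2.65, both with adjusted p = 0.641 with an estimated correlation. The testis list summed to 349 ± 325 CPM in founders and 527 ± 399 CPM in controls, and lost the preset call without male founder 3 (0.195), where its median was 0.40, against 4.01 and 3.3 without male founder 1 or 2. Without male founder 3, Hsp23 had −1.60 and GstD2 −2.01, and AttD had −5.46 without male control 3.

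For male control vs founder, edgeR called 3 genes with 480 at an unadjusted p under 0.05, DESeq2 called 68, limma on log2 CPM 40 and limma voom with sample quality weights 2672. Of 46 lists 15 passed with the preset correlation and 2 with an estimated one. The 3 calls were lost in a fit of the founder and control males alone, with adjusted p = 0.16 for Lsp1gamma and 0.107 for LysB and CG4835, and 0 genes were called without male control 1. Without male control 2 or 3, 1 gene was called (Lsp1gamma 0.0832 without male control 2, LysB 0.0517 without male control 3). CG4835 lost its call without any library but male founder 3, with an adjusted p up to 0.259. The log2 fold changes moved to −14.84 without male control 3 and −8.46 without male founder 2 for Lsp1gamma, −9.68 without male control 2 for LysB and −6.51 without male control 3 for CG4835. Without male control 1 the medians of visceral muscle and Imd genes were −0.55 and −0.30.

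In females edgeR called no gene in the same comparison. Lsp1gamma lay at 56.4 ± 18.1 CPM in founders and 0.389 ± 0.290 CPM in controls (log2 fold change −7.09 ± 1.26, adjusted p = 0.0514), with all founder libraries above all controls. CG15199 lay at 4.03 ± 3.04 and 162 ± 225 CPM (5.34 ± 0.98, adjusted p = 0.0514). Muscle genes were lower as groups. The 5 flight muscle genes had a median of −0.91 and the 17 visceral muscle genes a median of −0.80, and both lists passed with the preset and with an estimated correlation (adjusted p = 1.25e-05 and 0.0157 with an estimated correlation). Act88F was at least 139-fold lower in controls, and Mlp84B had −0.89 ± 0.31. In this comparison 3 flight muscle genes and 0 visceral muscle genes passed over the list alone. CG15199 had 2.99 without female control 2, and the flight muscle median was −1.94 without that library and −1.79 without female founder 2.

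Stress, immune and stem cell genes of the female founders and controls passed only over their own lists. Hsp23 lay at 44.1 ± 7.11 CPM in founders and 7.87 ± 1.37 CPM in controls, and LysB at 156 ± 88.1 and 10.3 ± 6.50 CPM. Heat shock genes (median −1.03, −1.17 at bounds) and lysozymes (median −0.86) had adjusted p = 0.304 and 0.234 with an estimated correlation, and lysozymes lost the preset call without female founder 1 or female control 3 (up to 0.314). The antibacterial peptide gene DptA had a log2 fold change of 5.78 ± 1.69, Tsf1 had 2.26 ± 0.57 and pirk −1.22 ± 0.36. Of 15 markers of intestinal progenitors, 2 passed over the list alone, among them Sox21a, a transcription factor of these cells (1.30 ± 0.41). The progenitor gene esg had 1.29 ± 0.49, and the list had a median of 0.63 and adjusted p = 0.419 with an estimated correlation. The ovary list had a median of −2.05 and adjusted p = 0.419 with an estimated correlation, and summed to 7996 ± 7613 CPM in founders. Its median was 0.03 without female control 2, −0.49 without female founder 3, −0.95 without female founder 2, −2.69 without female control 1, −3.21 without female control 3 and −5.14 without female founder 1. DptA had 3.76, pirk −1.82 and progenitors 1.06 without female control 2, and other libraries moved progenitors to 0.11 (female control 3), 0.33 (female founder 1) or 1.04 (female founder 2), heat shock genes to −0.65 or −0.64 (female founder 2 or 3), DptA to 7.23 (female founder 3) and Sox21a to 2.03 (female founder 1).

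For female control vs founder, 348 genes had an unadjusted p under 0.05, and DESeq2 called 49, limma on log2 CPM 21 and limma voom with sample quality weights 6133. Of 46 lists 24 passed with the preset correlation and 2 with an estimated one. By edgeR 4 genes were called without female founder 1 (Lsp1gamma 0.0472), 1 without female control 1 (CG15199 0.0165), 1 without female control 3 (CG15199 0.0314) and 3 without the 3 libraries with many unseen genes.

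**Figure D3:**
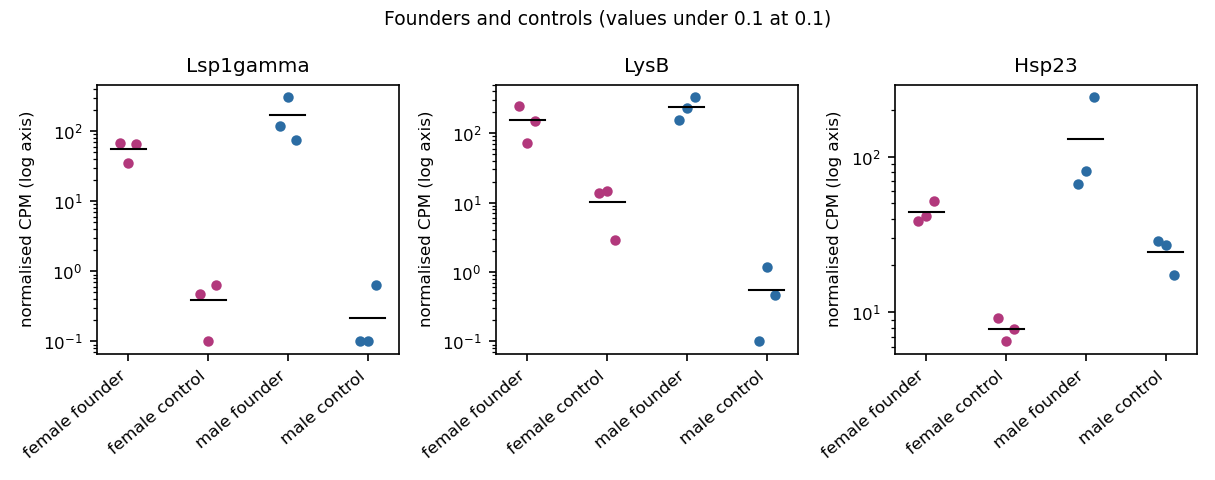
Normalised CPM of Lsp1gamma, LysB and Hsp23 in founders and controls of both sexes on log axes, with values under 0.1 drawn at 0.1. Points are libraries and lines are means of 3. Lsp1gamma lay at 56.4 and 168 CPM in female and male founders and at 0.389 and 0.214 CPM in controls.

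Each diet was compared with the control diet in females to ask how the gut responded to the compound. On capsaicin, the pungent compound of chili peppers, the 3 genes with the smallest p were Ldh, Ugt302E1 and CG17108. Ldh, lactate dehydrogenase, lay at 35.1 ± 7.45 CPM and at 90.1 ± 27.6 CPM in controls, a log2 fold change of −1.36 ± 0.34 that passed only over the glycolysis list alone (adjusted p = 0.00566). The glucuronosyltransferase gene Ugt302E1 had −1.85 ± 0.55 and CG17108 −1.42 ± 0.42. Of the cytochrome P450s, Cyp6a8 had 1.53 ± 0.51 without passing. All 4 Drosomycin-like peptides had negative estimates (median −1.57, −2.21 at bounds) and passed over the list alone. Drsl3 lay at 3.95 ± 1.38 CPM against 17.5 ± 20.5 CPM, a log2 fold change of −2.15 that was −0.53 without female control 2.

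Negative estimates were found for 82 of 87 ribosomal protein genes (median −0.82, −0.83 at bounds), 69 of 90 nuclear respiratory chain genes (median −0.88, −0.98 at bounds) and 29 of 35 glutathione S-transferases (median −0.74, −0.76 at bounds). These lists passed with the preset correlation on capsaicin. All 3 had adjusted p = 0.405 with an estimated correlation. The ovary list had a median of 1.20 and adjusted p = 0.634 with an estimated correlation, and the mitochondrial share was 9.87 ± 4.32% against 20.1 ± 8.01% in controls. With this share as a covariate the ribosomal median was −0.01 and the ovary median −0.49. Without female control 2, female control 3 or female capsaicin 1 the medians were −0.35, −1.34 and −0.49 for ribosomal proteins, −0.50, −1.41 and −0.51 for the respiratory chain, −0.36, −1.13 and −0.39 for glutathione S-transferases and −0.37, 2.54 and 0.20 for ovary. The ovary median was 3.01 without female capsaicin 3, and this list lost its preset call without female control 2, female capsaicin 1 or female capsaicin 2 (adjusted p up to 0.456). The eggshell gene Cp18 was at least 1510-fold higher on capsaicin without passing. In female capsaicin vs control, edgeR called 0 genes, with 241 (1.87%, fewer than by chance) at an unadjusted p under 0.05. DESeq2 called 19, limma on log2 CPM 0 and limma voom with sample quality weights 7341. Of 46 lists 23 passed with the preset correlation and 0 with an estimated one.

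On curcumin, 3 lists of digestive enzymes passed downward in females with the preset correlation, each with adjusted p = 0.521 with an estimated correlation. All 16 Jonah proteases had negative estimates (median −2.18), and 13 passed when adjusted over the list alone. Jon25Biii lay at 702 ± 488 CPM and at 4255 ± 3416 CPM in controls, and Jon74E had a log2 fold change of −3.53 ± 1.13. Of 16 trypsins 15 had negative estimates (median −1.70), among them betaTry at 3410 ± 1794 against 18707 ± 15004 CPM, and none passed over the list alone. Of 14 maltases and amylases 2 passed over the list alone (median −1.13), and the amylase gene Amy-p lay at 679 ± 489 CPM against 3254 ± 1879 CPM. Heat shock genes had a median of 1.33 (1.37 at bounds), with Hsp23 at 26.9 ± 26.5 against 7.87 ± 1.37 CPM, and ribosomal proteins had −1.18. The last 2 lists also passed with the preset correlation, with the same adjusted p of 0.521 with an estimated correlation. The maltase list did not pass without female control 2 (0.0697), nor the heat shock list without female curcumin 2 (0.19), where its median was 0.83 and Hsp23 had 0.56 in place of 1.76. The heat shock median was 0.70 without female control 2, where the ribosomal median was −0.72 and Jon74E had −2.21, Jon25Biii −1.88 (−2.60 with all libraries) and betaTry −1.63 (−2.46). Other moves were Jon74E at −5.74 and Amy-p at −3.02 (−2.26 with all) without female curcumin 3 and Jon25Biii at −3.21 without female curcumin 2. The Jonah median was −1.54 and −2.96 without female control 2 or 3, and the trypsin median −2.30 without female control 3.

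Single genes in females on curcumin passed at most over their lists. The mitochondrial superoxide dismutase gene Sod2 had −1.34 ± 0.41 and the fat body lipoprotein gene apolpp 2.88 ± 0.83, each passing over the list alone, while Cyp6w1 had 1.60 ± 0.43 without passing. Without female control 3 apolpp had 3.64. The 3 genes with the smallest p were CG1698 (−2.03 ± 0.46), the nucleoside transporter gene Ent2 (−1.57 ± 0.39) and CG11275 (−1.45 ± 0.36), each with an adjusted p of 0.513. Female curcumin 2 had the highest mitochondrial share of all. For female curcumin vs control, edgeR called 0 genes, with 1161 at an unadjusted p under 0.05, 5 with the mitochondrial share as a covariate, 37 by DESeq2, 0 by limma on log2 CPM and 5537 by limma voom with sample quality weights. Of 46 lists 19 passed with the preset correlation and 0 with an estimated one.

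On resveratrol, a stilbene known from grapes, females had lower estimates for CG17108 (12.9 ± 5.83 against 47.5 ± 21.9 CPM), the serine protease gene Ser7 (−2.20 ± 0.51) and the growth factor gene Idgf1 (11.8 ± 1.72 against 32.8 ± 3.94 CPM), all with an adjusted p of 0.934. The Imd inhibitor pirk had 1.21 ± 0.36 and passed over its list alone. All 15 markers of intestinal progenitors had positive estimates (median 0.69), and 32 of 35 glutathione S-transferases negative ones (median −0.57). The ovary list had a median of −1.44 (−2.23 at bounds), with the eggshell gene Vml at 0.0157 ± 0.0273 CPM against 22.5 ± 19.7 CPM. These lists passed with the preset correlation and had adjusted p = 0.716 with an estimated correlation, and 0 of their genes passed over the list alone. The ovary list did not pass without female control 3 (0.356), nor the glutathione S-transferases without female control 2 (0.103). The medians were −3.56 and 0 for ovary and −0.14 and −1.02 for glutathione S-transferases without female control 2 or 3, pirk had 1.80 without female control 2 and progenitors 1.30 without female control 3, and the ovary median was −0.87 without female resveratrol 1 and −2.34 without female resveratrol 2. In female resveratrol vs control, edgeR called 0 genes, with 246 at an unadjusted p under 0.05, DESeq2 30, limma on log2 CPM 0 and limma voom with sample quality weights 2342. Of 46 lists 15 passed with the preset correlation and 0 with an estimated one.

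On thymoquinone, a quinone of black seed, the gene CG17108 (FBgn0032285, chromosome 2L, 10692940 to 10694103) came closest to a call in females. It lay at 9.17 ± 2.28 CPM and at 47.5 ± 21.9 CPM in controls, a log2 fold change of −2.37 ± 0.44 (adjusted p = 0.0998), with all thymoquinone libraries below all controls. With the replicate block (adjusted p = 0.0328) and with median-of-ratios size factors (0.0433) it was the 1 gene called. Idgf1 had −1.35 ± 0.35 and CG10680 −1.31 ± 0.35. SPE, the protease that activates the Toll ligand, had −1.35 ± 0.40, and the sterol-binding genes Npc2g and Npc2h had −1.51 ± 0.43 and −2.07 ± 0.62, each passing over the list alone.

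Among groups of genes in females on thymoquinone, 14 of 15 Malpighian tubule markers (median −0.50), 69 of 90 nuclear respiratory chain genes (median −0.61, −0.68 at bounds) and 82 of 87 ribosomal protein genes (median −0.58) had negative estimates. The ovary list had a median of 2.46 and summed to 2832 ± 894 CPM against 1273 ± 1514 CPM in controls. All 4 passed with the preset correlation, ribosomal proteins not without female control 2 (0.234). Adjusted p was 0.381 with an estimated correlation for 3 of these lists and 0.506 for ribosomal proteins. Without female control 2 or 3 the medians were 0.32 and 3.69 for ovary, −0.22 and −1.16 for the respiratory chain and −0.11 and −1.09 for ribosomal proteins, and that of Malpighian tubule markers was −0.88 without female control 3. Without female thymoquinone 2 or 3 the respiratory chain had −0.40 and −1.06 and ribosomal proteins −0.35 and −1.07, and these had −0.34 without female thymoquinone 1. In female thymoquinone vs control, edgeR called 0 genes, with 173 at an unadjusted p under 0.05, against 30 by DESeq2, 0 by limma on log2 CPM and 5843 by limma voom with sample quality weights. Of 46 lists 20 passed with the preset correlation and 0 with an estimated one.

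In males on capsaicin, the genes with the smallest p were at or near 0. Ance-3, named as a relative of angiotensin converting enzyme, had 0 counts in all libraries on capsaicin and 3.08 ± 2.82 CPM in controls, at least 40.4-fold lower. The antisense gene asRNA:CR45812 was at least 12.2-fold lower, and CG10663 lay at 0.0223 ± 0.0387 against 0.868 ± 0.275 CPM. None passed, with an adjusted p of 1. All 31 testis genes had negative estimates (median −1.31), 78 of 87 ribosomal protein genes positive ones (median 0.45) and 23 of 35 glutathione S-transferases positive ones (median 0.21, 0.22 at bounds). These lists passed with the preset correlation and had adjusted p = 0.945 with an estimated correlation. All 3 lost the preset call without male control 3 or male capsaicin 1 (up to 0.899), testis genes also without male control 1 and glutathione S-transferases without male capsaicin 2. Without male control 1 or 3 or male capsaicin 1 or 3 the medians were 0.90, −0.04, 0.20 and 0.77 for ribosomal proteins and 0.46, −0.10, 0.09 and 0.36 for glutathione S-transferases, and that of testis was −0.21 without male capsaicin 1. The estimate of CG10663, −4.85 with all libraries, was −7.26 without male capsaicin 3. The testis list summed to 308 ± 310 CPM against 527 ± 399 CPM in controls. For male capsaicin vs control, edgeR called 0 genes, relative to a median shift of −0.20, with 581 at an unadjusted p under 0.05, and 10 without male capsaicin 3. DESeq2 called 15, limma on log2 CPM 9 and limma voom with sample quality weights 2971. Of 46 lists 6 passed with the preset correlation and 0 with an estimated one.

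In males on curcumin, the pigment of turmeric, the 3 genes with the smallest p were Cyp28a5, lncRNA:CR44138 and Cyp9b2, of which 2 belong to the cytochrome P450 family, whose members oxidise foreign compounds. Cyp28a5 (FBgn0028940, chromosome 2L, 13977302 to 13979569) lay at 398 ± 354 CPM and at 42.9 ± 7.02 CPM in controls, a log2 fold change of 3.21 ± 0.60. Cyp9b2 (FBgn0015039, chromosome 2R, 7130277 to 7132139) lay at 760 ± 618 against 185 ± 17.1 CPM (2.04 ± 0.43). Both passed over the cytochrome P450 list alone (adjusted p = 0.000681 and 0.00213) and not over all genes (0.117 and 0.244), and all libraries on curcumin lay above all controls. These were 2 of the 75 members, and the list had a median of −0.02, a mean of −0.10 and a test direction upward that did not pass (adjusted p = 0.2, and 0.97 with an estimated correlation). The list passed with the preset correlation without male control 1 (0.0111) or male curcumin 3 (0.0415). Cyp6a23 had 2.01 ± 0.60 without passing, and the glucuronosyltransferase gene Ugt37A2 had 2.24 ± 0.67 and passed over its list. Without male curcumin 2 the estimates were 2.18 for Cyp28a5, 1.13 for Cyp9b2, 1.17 for Cyp6a23 and 1.47 for Ugt37A2. The P450 median was above 0 without male control 1 (0.05) or male curcumin 3 (0.07) and −0.09 to −0.05 without the others.

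In males on curcumin, lncRNA:CR44138 lay at 53.3 ± 49.0 against 5.21 ± 3.76 CPM (3.36 ± 0.69, 2.27 without male curcumin 2 and 4.07 without male control 1) and LysE at 4.84 ± 1.98 against 53.0 ± 14.1 CPM. LysE passed over the lysozyme list alone (adjusted p = 0.0142). Accessory gland genes had negative estimates for 30 of 31, a median of −6.51 (−5.90, −7.70 and −5.62 without male curcumin 1, 2 or 3) and 22 that passed over the list alone, while the list had adjusted p = 0.489 with an estimated correlation. Acp95EF lay at 7.77 ± 9.5 against 569 ± 257 CPM (−6.19, and −7.87 without male curcumin 2). The accessory gland list summed to 3825 ± 1346 CPM against 8492 ± 4939 CPM in controls. Testis genes had a median of −1.32 and glutathione S-transferases of 0.26 (0.31 at bounds, −0.05 without male control 3 and 0.59 without male control 1), both with adjusted p = 0.97 with an estimated correlation. Neither passed with the preset correlation without male curcumin 1 (testis 0.0503), nor glutathione S-transferases without male control 3 (0.941).

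For male curcumin vs control, edgeR called 0 genes, relative to a median shift of −0.23, with 685 at an unadjusted p under 0.05. DESeq2 called 62, limma on log2 CPM 70, limma voom with sample quality weights 1572, and edgeR on the control and curcumin males alone 77. Without male curcumin 1, the 1 gene called was Cyp28a5 (adjusted p = 0.0305). With the mitochondrial share as a covariate or without the 3 libraries with many unseen genes the adjusted p of Cyp28a5 was 0.0346 and 0.0373. Over all alternatives for Cyp28a5, male curcumin vs control, it ran from 4.59e-06 by DESeq2 to 0.91 without male control 2. The fits with sample quality weights are not part of this range. Of 46 lists 3 passed with the preset correlation and 0 with an estimated one.

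**Figure D4:**
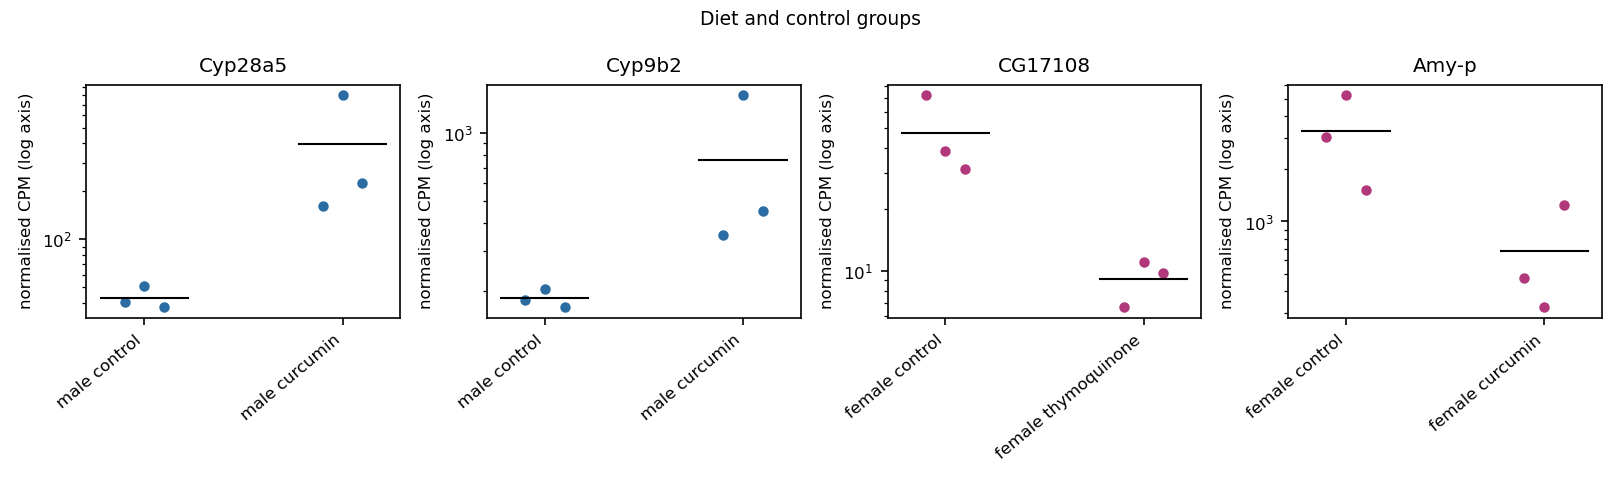
Normalised CPM of 4 genes in diet and control libraries on log axes: Cyp28a5 and Cyp9b2 in males on curcumin, CG17108 in females on thymoquinone and Amy-p in females on curcumin. Points are libraries and lines are means of 3. Cyp28a5 had means of 398 CPM on curcumin and 42.9 CPM on the control diet.

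In males on resveratrol, CG1673 lay at 22.3 ± 15.7 against 2.55 ± 3.08 CPM, aay at 73.2 ± 33.1 against 25.3 ± 10.4 CPM and the Bomanin immune gene BomS6 at 11.2 ± 6.42 against 73.5 ± 28.3 CPM. None passed, with an adjusted p of 1. Nuclear respiratory chain genes (81 of 90 estimates negative, median −0.56) and ribosomal protein genes (78 of 87 negative, median −0.47) passed with the preset correlation. So did regeneration signals of the JAK-STAT and EGFR pathways (median 0.74, Socs36E at 75.0 ± 71.5 against 30.4 ± 4.17 CPM) and TRP channels (median 1.17, Trpm at 20.5 ± 17.9 against 7.83 ± 5.68 CPM). The 4 lists had adjusted p = 0.953 with an estimated correlation, and 0 of their genes passed over the list alone. Without male resveratrol 2, the library with Sxl and ovary transcripts, the respiratory chain median was 0.08 and the ribosomal median 0.35, and with the mitochondrial share as a covariate they were 0.15 and 0.28, where both lists passed upward. These medians were −0.28 and −0.01 without male control 1, −0.85 and −0.98 without male control 3 and −0.91 and −0.96 without male resveratrol 1, and the ribosomal one was −0.78 without male resveratrol 3. Without male resveratrol 2 the JAK-STAT median was 0.06, the TRP median 0.52, Socs36E had 0.22 (1.30 with all libraries) and Trpm 0.41 (1.38), while without male control 1 the medians were 0.36 and 0.57, and without male resveratrol 1 that of JAK-STAT was 1.17. Trpm had 2.16 without male control 3, and CG1673 (3.08 with all) 4.75 without male control 3 and 2.35 without male resveratrol 3. The first 3 lists lost their preset calls without male control 1, and without male resveratrol 2 the other 3 lost theirs (adjusted p up to 0.837) while ribosomal proteins passed in the opposite direction. For male resveratrol vs control, edgeR called 0 genes, with 273 at an unadjusted p under 0.05, DESeq2 1, limma on log2 CPM 0 and limma voom with sample quality weights 2635. Of 46 lists 13 passed with the preset correlation and 0 with an estimated one.

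In males on thymoquinone, CG33511 lay at 3.86 ± 3.12 against 31.9 ± 5.03 CPM, and CG1632 and lncRNA:CR45591 were at least 8.26-fold and 10.0-fold lower than in controls. None passed, with an adjusted p of 1. The accessory gland list had a median of −2.72 on log2 CPM, and its test direction was downward, while 20 of 31 estimates of the count model lay above 0. The testis list had a median of −1.11, with 16 of 31 above 0. Both passed with the preset correlation and had adjusted p = 0.992 with an estimated correlation. Male thymoquinone 2, with 588 unseen genes, had 21.3 CPM of testis and 2427 CPM of accessory gland transcripts, and without it the medians were 0.72 for accessory gland and 0.46 for testis, and neither list passed (0.377 and 0.417). Without male thymoquinone 1 they were −4.84 and −2.31, and CG33511, −3.05 with all libraries, had −3.68. The accessory gland median was −3.97 without male thymoquinone 3. For male thymoquinone vs control, edgeR called 0 genes, with 262 at an unadjusted p under 0.05, and 1 without the 3 libraries with many unseen genes. DESeq2 called 5, limma on log2 CPM 0 and limma voom with sample quality weights 1545. Of 46 lists 4 passed with the preset correlation and 0 with an estimated one.

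The difference between the sexes in each diet response was tested itself, since the study asks about sex-specific responses. For curcumin, lncRNA:CR44138 had the smallest p, with 7.94 ± 3.06 CPM on the diet and 21 ± 8.9 CPM in controls in females and 53.3 ± 49.0 against 5.21 ± 3.76 CPM in males, a difference of −4.76 ± 0.93 on the log2 scale (adjusted p = 0.259). Cyp9b2 had a difference of −2.85 ± 0.60, Cyp28a5 of −3.06 ± 0.79 and CG10562 of −2.67 ± 0.63. Both P450 genes passed over their list alone (adjusted p = 0.00378 and 0.0194). Without male curcumin 2 the differences were −3.67 for lncRNA:CR44138, −1.94 for Cyp9b2 and −2.02 for Cyp28a5, and without male control 1 that of lncRNA:CR44138 was −5.47. On curcumin the Jonah proteases (median −2.23) and glucuronosyltransferases (median −1.09) had lower estimates in females than in males and accessory gland genes higher ones (6.56, with 26 of 31 members at 0 in some group), with adjusted p = 0.685 with an estimated correlation for each. The Jonah median was −1.60 and −3.03 without female control 2 or 3, −1.61 without female curcumin 1 and −2.94 without male curcumin 3, and that of accessory gland 7.91 and 5.74 without male curcumin 2 or 3.

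For the other diets lncRNA:CR44138 had differences of −3.16 ± 0.91 on resveratrol and −3.39 ± 0.92 on thymoquinone, against the same control libraries (−3.87 and −4.11 without male control 1, −2.16 on resveratrol without male resveratrol 3), and Idgf1 had −1.72 ± 0.49 on resveratrol. For capsaicin the leading genes were asRNA:CR45812, Ance-3 and CG3513, each with 0 counts in males on capsaicin. Further leading genes were near 0 CPM, such as Cpr92F on resveratrol and CG6996 and lin-28 on thymoquinone. On capsaicin the ribosomal proteins (median −1.30), glutathione S-transferases (−0.85) and Jonah proteases (−1.31) had lower estimates in females than in males, with adjusted p = 0.557 with an estimated correlation for each. Without female control 2 ribosomal proteins had −0.84, and without female control 2 or 3 glutathione S-transferases had −0.48 and −1.30 and Jonah proteases −0.58 and −2.28. Without male control 3 ribosomal proteins had −0.82 and glutathione S-transferases −0.42, without female capsaicin 1 glutathione S-transferases had −0.54 and Jonah proteases −0.28, and without female capsaicin 3 Jonah proteases had −2.41. The ovary list had medians of −1.85 on resveratrol (0.976) and 2.62 on thymoquinone (0.924), and ribosomal proteins −0.69 on thymoquinone (0.924), each p with an estimated correlation. These 3 lost the preset call without single libraries: the ovary list on resveratrol without female control 3 or female resveratrol 1 (up to 0.231) and on thymoquinone without female control 2 (0.284), and ribosomal proteins without female control 2 or male control 3 (up to 0.705). Without female control 2 or 3 the ovary medians were −3.65 and −0.43 on resveratrol (−2.60 without female resveratrol 2) and 0.46 and 4.29 on thymoquinone, and the ribosomal median was −0.24 and −1.20, −1.12 and −0.19 without male control 1 or 3, and −1.14 without female thymoquinone 3.

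For age, the Jonah proteases had a median difference of 2.43 between females and males, with 5 of 16 passing over the list alone and adjusted p = 0.49 with an estimated correlation. It was 3.35 without female founder 1 and 1.81 and 3.3 without female control 2 or 3. Jon66Cii lay at 17 ± 16.1 CPM in female founders and 76.6 ± 72.1 CPM in female controls, and at 21.2 ± 9.72 and 4.11 ± 2.90 CPM in males. Lysozymes had a median difference of 1.92 (adjusted p = 0.0767 with an estimated correlation), and LysB of 4.83 ± 1.42, passing over the list alone. Phk-3 (2.89 ± 0.69), CG5550 (3.65 ± 1.01) and Tsp26A (−2.77 ± 0.77) had the smallest p without passing, with an adjusted p of 1. The difference was 2.95 for CG5550 and 3.47 for Jon66Cii (4.56 with all libraries) without female control 2, without male control 2 it was 5.76 for LysB and 5.21 for Jon66Cii, and without female founder 1 5.55 for Jon66Cii.

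By edgeR 0 genes were called for the difference between the sexes in any of these 5 tests. At an unadjusted p under 0.05 there were 456 genes in the sex by capsaicin interaction, 879 in the sex by curcumin interaction, 157 in the sex by resveratrol interaction, 200 in the sex by thymoquinone interaction and 264 in the sex by age interaction. In the same order DESeq2 called 19, 43, 24, 18 and 20, limma on log2 CPM 0, 0, 0, 0 and 4, and limma voom with sample quality weights 5837, 3791, 1576, 2608 and 2741. Median log2 shifts of 0.41, 0.38 and −0.17 lay under the capsaicin, curcumin and age differences. Of 46 lists 15, 16, 1, 13 and 21 passed with the preset correlation and 0 with an estimated one.

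No gene was shared between diets by edgeR. The number of female genes called in 2 or more diets was 0 and that of male genes called in 2 or more diets was 0, where 20 simulations of unchanged groups against the same controls gave a mean of 0 and a maximum of 0, and independent lists would share 0. By DESeq2 the numbers were 23 and 8, by limma on log2 CPM 0 and 4 and by limma voom with sample quality weights 6273 and 2071. Across 12855 genes, which are not independent replicates, the fold changes of females and males had a covariance of −0.149 on capsaicin (r = −0.08), −0.137 on curcumin (r = −0.06), 0.131 on resveratrol (r = 0.09) and 0.0329 on thymoquinone (r = 0.02). The sexes have separate controls, so no covariance from shared controls enters these values. Leaving out 1 library could turn the sign on all diets but resveratrol, where the covariance came down to 0.0198 (ranges are given below).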

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

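Among the tests below, those of the group effect on ovary transcripts, of the 3 libraries with many unseen genes, of the mitochondrial share as a covariate and of the fat body list were chosen only after the results they concern were seen.

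Interactions with sex called 15, 16, 1, 13 and 21 lists with the preset correlation for capsaicin, curcumin, resveratrol, thymoquinone and age, and 0 with an estimated correlation. The 11 of them that the report names follow. On capsaicin, females had lower estimates than males for ribosomal proteins (median difference −1.30), glutathione S-transferases (−0.85) and Jonah proteases (−1.31, −0.28 without female capsaicin 1). On curcumin, the difference was 6.56 for accessory gland genes, −2.23 for Jonah proteases and −1.09 for UDP-glycosyltransferases. The ovary list had −1.85 on resveratrol (−0.43 without female control 3) and 2.62 on thymoquinone (0.46 without female control 2), where ribosomal proteins had −0.69 (−0.19 without male control 3). Other libraries that moved these medians are named in the report. For age, Jonah proteases had 2.43 and lysozymes 1.92. Of the 31 accessory gland genes 26, and of the 29 ovary genes 18 and 19, had 0 counts in some group, so that their fitted differences depend on the prior count.

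The first pattern is the spread of ovary transcripts between female gut libraries. Ovary tissue carried over at dissection may contribute, since eggshell genes such as Vm26Ab reached 371 ± 404 CPM in female founders, and since the ovary list moved with the DNA replication and mitosis list over 18 female libraries with group means subtracted. Pearson r was 0.935 (permutation p = 4.0e-05, 8.0e-05 adjusted over 2 relations) and Spearman rho 0.913 (permutation p = 4.0e-05), r was 0.946 without female founder 1 and female capsaicin 3, and within replicate numbers 1, 2 and 3 it was 0.939, 0.959 and 0.961 (exact permutation p of 0.00278, 0.0167 and 0.00694). The ovary list also moved against the log2 mitochondrial share, with r = −0.762 (permutation p = 0.0119, adjusted 0.0119), rho = −0.765 (permutation p = 0.00632), −0.607 without female curcumin 2 and female founder 1, and −0.825, −0.658 and −0.813 within replicate numbers (exact permutation p of 0.0431, 0.132 and 0.0306). Whether diet or age contributed cannot be told apart from this spread with 3 libraries a group (permutation p = 0.451 between the 6 female groups), and of the 29 ovary genes 0 were in another list and 3 reached 1 CPM as a median in males.

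The second pattern is the low number of genes called between diets. The spread between replicates may account for it, as 34.8% of the genes changed 4-fold were called in simulated libraries with this spread. The changed genes were drawn from those with at least 5 CPM in controls. Genes were simulated as independent of each other, unlike those of the real libraries. Whether the 3 libraries with many unseen genes or the mitochondrial share contributed cannot be told apart, since the 8 diet comparisons together had 2 calls without these libraries and 6 with the share as a covariate, and a test that calls so few of the changed genes can give such counts in either case. The many calls of the fit with sample quality weights are likely due to weights held by single libraries, since in 6 of 8 diet comparisons another split of the 6 libraries called as many genes (for female capsaicin 7341 and 7771), and the largest share of a group's weight on 1 library had a median of 83.2%. A diet effect too small for 3 libraries stays open and was not tested.

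The third pattern is the lower level of Lsp1gamma, LysB, CG4835 and muscle genes in controls than in founders. Carry-over of adult fat body cannot be told apart in males, since the members of the fat body list went both ways (7 positive and 8 negative estimates, median 0.49, mean −0.11, sums without TMM scaling of 231 ± 120 CPM in founders and 286 ± 245 CPM in controls). In females the list had a median of −0.47 (adjusted p = 0.214) and sums of 8966 ± 6014 CPM in founders and 3526 ± 1770 CPM in controls. Remains of larval tissue may still be involved, because the larval fat body genes Fbp1 and Fbp2 lay at 1.06 ± 0.95 and 1.65 ± 1.81 CPM in male founders and at 0 in male controls, which was not tested further. The mitochondrial share is argued against, since 3 of 3 genes were called with it as a covariate, and age and the change of food stay open, as the design joins them.

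The number of genes called was also counted over all splits of the same libraries, and 10 splits of 6 libraries are too few for a share under 0.05. Where the real count was 0, all 10 splits were as large by construction. The real and highest other counts on capsaicin, curcumin, resveratrol and thymoquinone were 0 and 2, 0 and 0, 0 and 0, and 0 and 0 in females and 0 and 462, 0 and 0, 0 and 0, and 0 and 0 in males. For age they were 0 and 747 in females and 3 and 0 in males (1 split). For sex they were 1163 and 220 in founders and 1723 and 0 in controls (1 split each). The counts of 462 and 747, against real counts of 0, point to a structure of the samples. The split with 747 calls parted female controls 1 and 2 and female founder 1 from the rest. Their ovary sums were 856, 11.9 and 24.0 CPM, against 2953 to 15191 CPM. The split with 462 calls parted male capsaicin 1 and 2 and male control 1 from the rest. Their testis sums were 41.4, 235 and 255 CPM, against 340 to 985 CPM. Whether organ content made these calls was not tested. Replicate numbers pair the libraries across groups, and among the 4 splits that part all 3 pairs the highest other count was 2 for females and 3 for males on capsaicin and 0 for the 10 other comparisons.

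For the lists called with the preset correlation the 10 splits are too few as well. The real and highest other numbers were 23 and 25, 19 and 20, 15 and 22, and 20 and 21 in females on the 4 diets (3, 3, 7 and 4 splits as large) and 6 and 12, 3 and 11, 13 and 20, and 4 and 17 in males (7, 9, 7 and 10 splits). For age they were 24 and 25 in females and 15 and 18 in males (2 and 3 splits), and for sex 16 and 24 in founders and 13 and 19 in controls (3 and 7 splits).

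For the differences between the sexes and the genes shared by diets, 21 splits were counted. The interactions had 0 genes, so that 21 of 21 splits were as large by construction and say nothing about chance, with a highest other count of 167 for capsaicin, 15 for age and 0 for the other 3. The count of 167 points to a structure of the samples as well, and which libraries that split parted was not examined. For 2 or more diets the counts were 0 and 0 for both sexes, and the 21 splits say nothing there either. Lists of the interactions numbered 15, 16, 1, 13 and 21 for capsaicin, curcumin, resveratrol, thymoquinone and age, with 25, 21, 22, 23 and 25 as the highest other and 12, 8, 21, 13 and 3 splits as large, so that chance was not excluded. The covariances of −0.149, −0.137, 0.131 and 0.0329 had 11, 12, 12 and 18 splits as large in size, with 0.65, 0.62, 0.398 and 0.589 as the highest other, and chance was not excluded here either.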

How the results depend on the processing

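Limma, the sample quality weights, the mitochondrial share as a covariate, the evenly expressed genes, DESeq2 with filtering tuned at 0.1 and the fit without 3 libraries were chosen only after the data were seen. No filter, the filter at 5 CPM in 3 libraries and a log2 fold change of at least 1 kept all 19 counts within 1.5 times. The number of genes called moved by more with each of the others, and the cause was not tested unless the setting shows it, as with fewer genes or libraries tested. What depth limits apart from replicate spread was not tested, as the simulated libraries had both as measured.

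The comparisons are, in order, female capsaicin vs control, female curcumin vs control, female resveratrol vs control, female thymoquinone vs control, male capsaicin vs control, male curcumin vs control, male resveratrol vs control, male thymoquinone vs control, female control vs founder, male control vs founder, founder female vs male, control female vs male, sex by capsaicin interaction, sex by curcumin interaction, sex by resveratrol interaction, sex by thymoquinone interaction and sex by age interaction, then female genes called in 2 or more diets and male genes called in 2 or more diets. DESeq2 called 19, 37, 30, 30, 15, 62, 1, 5, 49, 68, 1985, 2371, 19, 43, 24, 18, 20, 23 and 8. With filtering tuned at 0.1 it called 19, 28, 30, 30, 15, 46, 1, 5, 49, 63, 1985, 2371, 19, 43, 23, 16, 21, 23 and 8. Limma voom with sample quality weights called 7341, 5537, 2342, 5843, 2971, 1572, 2635, 1545, 6133, 2672, 6625, 8141, 5837, 3791, 1576, 2608, 2741, 6273 and 2071. With weights and at least 5 CPM in 3 libraries it called 6074, 4962, 2150, 5349, 1857, 1121, 1692, 501, 4961, 2300, 5033, 5619, 4569, 3562, 981, 1934, 2110, 5538 and 1015. Limma on log2 CPM moved the counts of male capsaicin to 9, male curcumin to 70, female age to 21, male age to 40, founder sex to 340, the age interaction to 4 and male genes in 2 or more diets to 4.

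For female curcumin vs control, male curcumin vs control, female control vs founder and male control vs founder, the mitochondrial share as a covariate gave 5, 1, 4 and 36 genes, and with at least 5 CPM in 3 libraries 7, 1, 4 and 38. DESeq2 size factors gave 1 gene for female thymoquinone vs control and 7 for male control vs founder. The replicate block gave 1 for female thymoquinone vs control and 521 for founder female vs male, and it changed no other count by over 1.5 times. Among named genes the block changed 5 calls, of which CG17108 was gained and Vm26Ab, Cp16, Cp18 and CycA were lost, and among lists none. With only the groups compared, male curcumin vs control had 77, male control vs founder 0 and founder female vs male 61, of which 57 were among the 1163. Evenly expressed genes, fewer in number, gave 1 for male curcumin vs control, 2 for female control vs founder, 21 for male control vs founder, 6 for founder female vs male and 173 for control female vs male. Without the 3 libraries with many unseen genes there was 1 for male curcumin vs control, 1 for male thymoquinone vs control and 3 for female control vs founder.

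Leaving out 1 library gave 0 to 10 genes for male capsaicin, 0 to 1 for male curcumin, 0 to 4 for female age, 0 to 3 for male age, 32 to 1305 for founder sex and 101 to 1428 for control sex, with the libraries given beside each result. The other counts stayed at 0. Covariances between the sexes ran from −0.381 to 0.106 on capsaicin, −0.291 to 0.152 on curcumin, 0.0198 to 0.395 on resveratrol and −0.068 to 0.0965 on thymoquinone.

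Lists whose median or test turned its direction did so with the mitochondrial share as a covariate, without the 3 libraries or without 1 library. With the share, ribosomal proteins had −0.01 and an upward test on female capsaicin, where the ovary list had −0.49, and on male resveratrol the respiratory chain had 0.15 and ribosomal proteins 0.28. Without the 3 libraries, accessory gland genes had 0.62 and testis genes 0.37 on male thymoquinone. Without 1 library the ovary list on female capsaicin ran from −0.37 to 3.01, with 0.20 and a downward test without female capsaicin 1. It ran from −5.14 to 0.03 for female age, and on female resveratrol it came to 0 without turning. Ribosomal proteins ran from −0.04 to 0.90 on male capsaicin and cytochrome P450s from −0.09 to 0.07 on male curcumin. Glutathione S-transferases ran from −0.10 to 0.46 on male capsaicin and from −0.05 to 0.59 on male curcumin. On male resveratrol the respiratory chain ran from −0.91 to 0.08 and ribosomal proteins from −0.98 to 0.35, with −0.01 and an upward test without male control 1. On male thymoquinone accessory gland genes ran from −4.84 to 0.72 and testis genes from −2.31 to 0.46. With an estimated correlation 58 of 63 lists lost the call, and 5 kept their side of the threshold.

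Of 140 gene results in the text, no setting turned a direction. DESeq2 kept 101 on their side and added 39 calls, and limma on log2 CPM kept 123, added 14 and lost 3. A fit of only the groups compared lost 10 calls and added 2, no filter lost 4, and the mitochondrial share lost 5 and added 9.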

Other observations

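Diets were also compared with each other within a sex, at doses that differ between compounds. In males, Cyp28a5 was the gene with the smallest p in 3 of 6 comparisons, higher on curcumin than on resveratrol by 3.08 on the log2 scale (adjusted p = 0.199) and than on thymoquinone by 3.08 (adjusted p = 0.198), and at −2.91 on capsaicin relative to curcumin (adjusted p = 0.394). The stress-responsive transcription factor gene Ets21C had −3.80 on capsaicin relative to resveratrol (adjusted p = 0.601). In females, Ser7 had 2.63 on curcumin relative to resveratrol (adjusted p = 0.245), Cyp6a8 had 1.89 on capsaicin relative to resveratrol and the eggshell gene Vml had −11.22 on resveratrol relative to thymoquinone. Sxl had 3.06 in males on resveratrol relative to thymoquinone, where male resveratrol 2 held 59.0 CPM of Sxl without TMM scaling.

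By edgeR 0 genes were called in each of these 12 comparisons, which DESeq2 and limma were not run on. At an unadjusted p under 0.05 there were 312 genes between capsaicin and curcumin in females and 790 in males, 222 and 1043 between capsaicin and resveratrol, 175 and 584 between capsaicin and thymoquinone, 652 and 1564 between curcumin and resveratrol, 437 and 741 between curcumin and thymoquinone, and 164 and 500 between resveratrol and thymoquinone. Chance gives 0.05 of genes, and a p over the threshold does not show that compounds act alike.

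Genes whose 3 libraries of a group did not overlap the 3 of the other numbered 1635 (12.7%) for males on curcumin and 1619 (12.6%) for male controls against founders, where chance gives 10%. In females they numbered 1132 (8.81%) on curcumin and 616 (4.79%) for controls against founders. On capsaicin, resveratrol and thymoquinone the shares were 4.39%, 6.74% and 4.44% in females and 8.04%, 7.65% and 4.12% in males, and between the sexes 15% in founders and 26.1% in controls.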
